A study of Homo sapiens with 33 samples.

How the data were processed

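Total RNA from skin biopsies kept in RNAlater was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The authors deposited a table of intensity values on a linear scale, in which array means were alike and batches were not adjusted, and the submitters' processing notes name affy and MAS5. The authors also deposited a table of log2 values adjusted for batch, per its title, by a method not given in the sources used here. Versions of both tools were not given in the sources used here. Each probe set carried the identifier of 1 Entrez gene. Signal over background per probe set was not given in the tables used here.

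Both tables held 12136 probe sets, 62 of them controls and 12074 with an Entrez identifier, of which 12040 were named through the RefSeq gene table of assembly GRCh38.p14 and 34 kept their identifier. No per-sample column was left unmatched to a sample. Because all genes had 1 probe set, the choice among several probe sets of a gene did not arise. XIST and Y-linked genes (19) were left out, and so were the 25% of genes with the lowest mean over all arrays, which left 9049 genes.

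The unadjusted values were analysed as log2(intensity + 16), and fold changes are on that scale, which understates the change of dim genes. Groups came from the diagnosis in the labels. A linear model with group and batch as fixed terms was fitted to all 33 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), so that the 11 healthy arrays of batches 4 and 5 added to the estimate of the spread only, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The model was tested on simulated data with the layout and spreads of this comparison and 9049 genes. It recovered 92.2% of genes changed by a log2 fold change of 1 and 98.0% of those changed by 2, with 4.65% of calls false, and camera called 10 of 10 lists that were moved and 0 of 10 that were not. The simulation had no correlation between genes.

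The gene lists, the tests and the rule for named genes were fixed before the data were examined. Of 30 lists 29 had at least 5 tested members and were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which tests whether the genes of a set move one way without comparing them with other genes. Named were the 8 highest and 8 lowest log2 fold changes past the threshold with the same sign in batch 2 alone, which holds by construction with a batch term, up to 3 members past the threshold with the largest change in each called list, the member with the smallest p in each other list, and 18 genes named in advance. List scores for correlations were means of z-scores over the 18 SSc arrays, tested with 100000 permutations. Single values were compared with exact permutation tests.

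Alternatives covered the batch term, the deposited table, between-array normalization, the filter, the pseudocount, array weights, the eBayes prior, an RNA quality covariate, the set test and leaving out each healthy array of batch 2. For batch as a random effect and for the robust prior the list test was run on the fit's own statistics, which gave the same 14 lists as camera in the main setting. Leaving out each SSc array, the ACTB ratio as a covariate and splitting the SSc arrays by a letter A at the end of the title were chosen after seeing the data.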

Results

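Gene expression was measured with Affymetrix arrays in total RNA from skin biopsies. The series holds 33 arrays, 18 of skin from patients with diffuse cutaneous systemic sclerosis (SSc) and 15 of skin from healthy controls. SSc is an autoimmune disease in which the skin hardens through deposition of connective tissue. The labels assign each array to a batch. All 18 SSc arrays and 4 healthy arrays (healthy replicates 12 to 15) were in batch 2, while 3 healthy arrays were in batch 4 and 8 in batch 5. Mean signal per array lay between 697 and 761 intensity units, and no 2 arrays held identical values. Correlations between arrays over the 9049 genes tested ranged from 0.874 to 0.975. The labels do not say whether each biopsy came from a separate donor, so p-values measure the spread between these arrays. The number of arrays, above all the 4 healthy arrays of batch 2, limits the precision.

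The main comparison asked which genes differ between SSc and healthy skin. SFRP4, a secreted modulator of Wnt signalling, rose by a log2 fold change of 3.16 ± 0.39 (SE), from 5.75 ± 0.69 (SD, n = 4) in healthy skin of batch 2 to 8.91 ± 0.77 (SD, n = 18) in SSc skin (limma, adjusted p = 1.15e-05), and all 18 SSc arrays lay above the 4 healthy ones. THY1, a surface glycoprotein of fibroblasts, rose by 1.94 ± 0.23 (limma, adjusted p = 1.15e-05), and NID2, a basement membrane protein, by 1.77 ± 0.25 (limma, adjusted p = 8.27e-05). NOX4, an NADPH oxidase, rose by 2.14 ± 0.39. SERPINE2, a protease inhibitor, rose by 1.84 ± 0.32, CCN2, the connective tissue growth factor, by 1.82 ± 0.34, and LAMP5 by 1.81 ± 0.34. WIF1, a secreted inhibitor of Wnt ligands, fell by 2.09 ± 0.51 on the log2 scale, from 10.25 ± 0.93 (SD, n = 4) to 8.16 ± 0.91 (SD, n = 18; limma, adjusted p = 0.0221), with 15 of 18 SSc arrays below all 4 healthy ones.

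Other genes with large falls were PCOLCE2, an enhancer of procollagen processing (log2 fold change -1.47 ± 0.34), TSPAN8, a tetraspanin (-1.38 ± 0.35), the cation channel gene MCOLN3 (-1.24 ± 0.25), IGFBP6, which binds insulin-like growth factors (-1.23 ± 0.27), the zinc finger gene ZNF273 (-1.09 ± 0.28) and the matrix metalloproteinase gene MMP27 (-1.07 ± 0.25). In all, 220 of 9049 genes passed an adjusted p of 0.05 in limma with batch as a term, 169 higher and 51 lower in SSc. Of these, 58 rose and 12 fell by a log2 fold change of at least 1. An unadjusted p under 0.05 was reached by 1648 genes, or 18.2%. With batch as a term the difference rests on the 18 SSc and 4 healthy arrays of batch 2, and a fit of those 22 arrays alone, which has the same fold changes by construction and its own spread, called 104 genes higher and 27 lower.

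**Figure D1:**
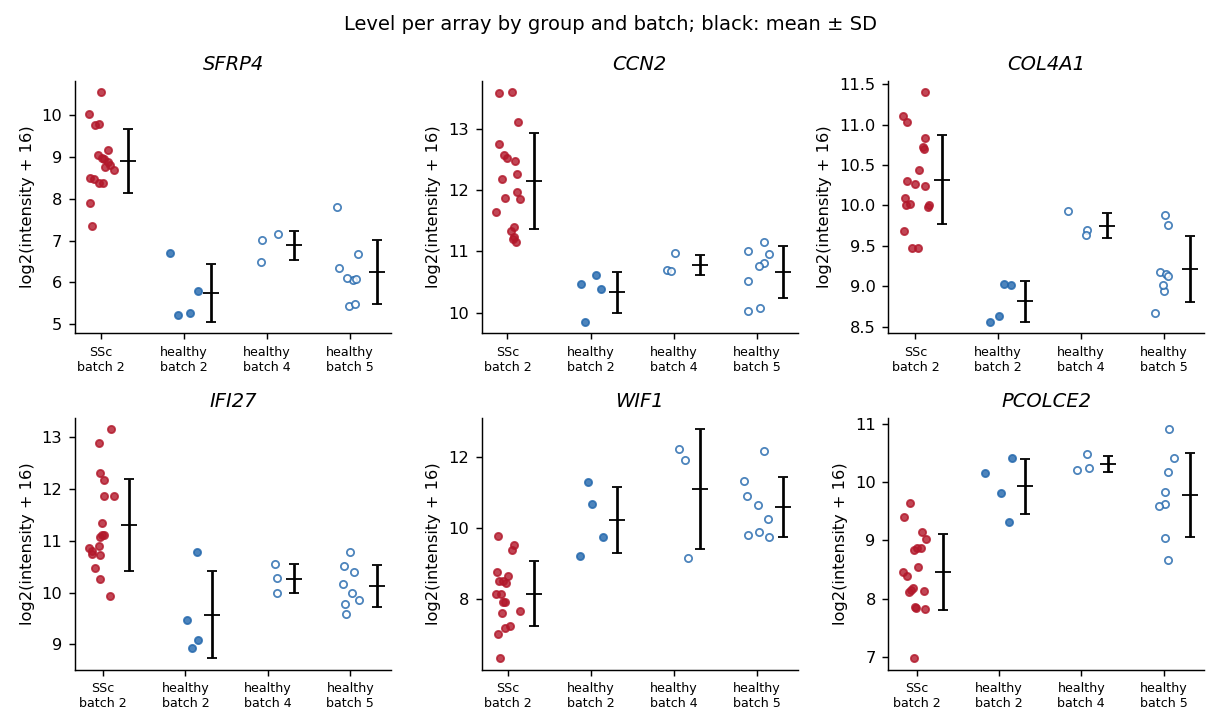
Level of 6 genes on each array as log2(intensity + 16), by group and batch, with filled points for batch 2, open points for batches 4 and 5, and bars for the mean ± SD. All 18 SSc arrays lay above the 4 healthy arrays of batch 2 for SFRP4, CCN2 and COL4A1, 13 did for IFI27, and 15 and 16 lay below them for WIF1 and PCOLCE2.

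The count depended on single arrays. The 220 genes became 131 without healthy replicate 12, 79 without healthy replicate 13, 64 without healthy replicate 14 and 99 without healthy replicate 15, and they became 336 without SSc replicate 11. Of the 38 named genes past the threshold, 14 kept their call in each of the 4 fits that lacked a healthy array: THY1, SFRP4, COL15A1, NID2, COL4A1, ASPN, SERPINE2, CFI, PECAM1, NOX4, CCN2, LAMP5, ANGPT2 and COL5A2. TIMP1, CDH11, C1QB and RGS5 lost theirs in each of those 4 fits. Without healthy replicate 12, CCN1, LUM, PLVAP, COL1A1, WIF1 and TSPAN8 also lost it (limma, adjusted p of the 10 lost calls 0.0519 to 0.124). Without healthy replicate 13, BST2, CD14, PCOLCE2, IFI27, MMP27, PLVAP, COL1A1, WIF1, ISG15, ZNF273 and TAGLN were among those that did (0.0504 to 0.227 for 16 genes in all). Without healthy replicate 14, MCOLN3, CALD1, IGFBP6, CCN1, CD14, PCOLCE2, IFI27, MMP27, PLVAP, COL1A1, TSPAN8, ISG15, ZNF273 and TAGLN were among those that did (0.0528 to 0.189 for 20 genes in all). Without healthy replicate 15, MCOLN3, IGFBP6, IL6, PCOLCE2, IFI27, WIF1, TSPAN8, ISG15, ZNF273 and TAGLN were among those that did (up to 0.134 for 15 genes in all). CDH11 also lost its call without SSc replicates 1, 9, 12, 13, 14, 16, 17 and 18 in turn, and C1QB without SSc replicates 1, 2, 9, 10 and 12 to 18 in turn (highest adjusted p 0.0571 and 0.063), and C1QB with batch as a random effect (0.0695). In batch 2 alone IFI27, MMP27, ISG15, TIMP1, TAGLN, CDH11 and C1QB had adjusted p between 0.0518 and 0.0964.

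Collagen genes rose as a group. Of 16 tested, 7 rose and none fell over all genes, 11 rose when adjusted over the list alone, and the median log2 fold change was 1.02 (camera, adjusted p = 9.95e-12; adjusted p = 0.167 with an estimated correlation). COL4A1, a chain of basement membrane collagen, rose by 1.51 ± 0.25 (limma, adjusted p = 0.00112), COL15A1 by 1.36 ± 0.18 and COL5A2, a chain of a fibrillar collagen, by 1.29 ± 0.27. COL1A1, a chain of the main fibrillar collagen of skin, rose by 1.24 ± 0.30 (limma, adjusted p = 0.0206), and its log2 fold change was -0.19 when batch was left out of the model and 0.73 with batch as a random effect (adjusted p = 0.157). COL1A2 (0.35 ± 0.16, adjusted p = 0.228 in limma) and COL3A1 (0.41 ± 0.15, adjusted p = 0.137 in limma) did not pass, although COL3A1 did without SSc replicate 11 (adjusted p = 0.0472). Mean levels of COL1A2 and COL3A1 were already 13.87 and 13.43 in healthy skin.

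Other extracellular matrix genes were higher as a group, with 4 of 26 past the threshold, all higher, a median of 0.62 and 14 higher and 2 lower when adjusted over the list alone (camera, adjusted p = 5.76e-08; adjusted p = 0.278 with an estimated correlation). ASPN, a small leucine-rich proteoglycan, rose by 1.77 ± 0.31, LUM, another of that family, by 1.29 ± 0.29, and TIMP1, an inhibitor of matrix metalloproteinases, by 0.93 ± 0.24. COMP, cartilage oligomeric matrix protein, had a log2 fold change of 2.01 ± 0.67 and missed the threshold (limma, adjusted p = 0.0935), but passed with the ACTB ratio of 3' to 5' signal as a covariate (3.15, adjusted p = 0.0419). TNC had 0.96 ± 0.34 (adjusted p = 0.122 in limma), and POSTN, a matricellular protein, had -0.13 ± 0.13 (adjusted p = 0.671 in limma). In the TGF-beta response list 4 of 15 genes rose, 5 when adjusted over the list alone, with a median of 0.27 (camera, adjusted p = 1.5e-05; adjusted p = 0.169 with an estimated correlation). NOX4 and CCN2 were among the 4, while THBS1 had 1.19 ± 0.39 (adjusted p = 0.0919 in limma). Fibroblast markers were higher with a median of 0.26, and 2 of 11, THY1 and CDH11 (0.80 ± 0.22), rose, 5 when adjusted over the list alone (camera, adjusted p = 0.000511; adjusted p = 0.278 with an estimated correlation). The fibroblast call was lost with batch as a random effect (median 0.047, adjusted p = 0.0629), and without a batch term the fibroblast median was -0.17.

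Genes of the type I interferon response were higher throughout. All 33 tested had a positive log2 fold change, with a median of 0.60, and 5 rose over all genes and 21 when adjusted over the list alone (camera, adjusted p = 1.02e-14; adjusted p = 0.204 with an estimated correlation). IFI27 rose by 1.74 ± 0.40 (limma, adjusted p = 0.0146), BST2, which tethers enveloped viruses to the cell, by 1.40 ± 0.28, and ISG15, a ubiquitin-like modifier, by 1.37 ± 0.35. IFI44 had 0.98 ± 0.30 (limma, adjusted p = 0.0697). Its adjusted p was 0.0447 without SSc replicate 5 and 0.0411 without SSc replicate 11. IFI44 also passed with batch as a random effect (0.0292), in the batch-adjusted table with a batch term (0.0411) and with array weights (0.0319). With the GAPDH or ACTB ratio of 3' to 5' signal as a covariate its adjusted p was 0.0342 or 0.0182. IFI44 did not pass in batch 2 alone (limma, adjusted p = 0.139). Nor did it in the 4 fits that each lacked a healthy array of batch 2 (0.117 to 0.206).

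Macrophage markers had positive log2 fold changes in all 20 genes tested, with a median of 0.64. CD14, a co-receptor for bacterial lipopolysaccharide, rose by 1.17 ± 0.26 and C1QB, a chain of complement C1q, by 1.12 ± 0.31 (limma, adjusted p = 0.0122 and 0.049), and 13 of the 20 rose when adjusted over the list alone (camera, adjusted p = 5.24e-09; adjusted p = 0.278 with an estimated correlation). MS4A4A (0.78 ± 0.31), SIGLEC1 (0.41 ± 0.28) and the chemokine gene CCL18 (0.52 ± 0.76) did not pass. Among 13 chemokine and cytokine genes IL6 rose by 1.33 ± 0.29, CCL2 had 0.92 ± 0.34 (adjusted p = 0.137 in limma; 1.18 and 0.0207 with batch as a random effect), and 4 rose when adjusted over the list alone, with a median of 0.39 (camera, adjusted p = 0.00336; adjusted p = 0.278 with an estimated correlation). Of 10 complement genes CFI, a protease that inactivates C3b, rose by 1.11 ± 0.20, and 4 rose when adjusted over the list alone, with a median of 0.50 (camera, adjusted p = 0.00288; adjusted p = 0.301 with an estimated correlation). Macrophage, chemokine and cytokine, and complement genes did not pass as groups by a permutation test of list means chosen after seeing the data. There adjusted p was 0.117, 0.228 and 0.119 (exact permutation).

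Markers of blood vessels rose. Endothelium held 7 risers among 16 genes, 11 when adjusted over the list alone, with a median of 0.65 (camera, adjusted p = 9.95e-12), and it alone of the 14 called lists passed with an estimated correlation (adjusted p = 0.0386 with an estimated correlation). ANGPT2, a regulator of vessel remodelling, rose by 1.15 ± 0.23, the adhesion molecule gene PECAM1 by 0.82 ± 0.15 and PLVAP, a protein of endothelial diaphragms, by 0.82 ± 0.19. Pericyte and smooth muscle genes were positive in all 16 tested, with a median of 0.49, and 4 rose, 6 when adjusted over the list alone (camera, adjusted p = 7.98e-07; adjusted p = 0.204 with an estimated correlation). Without a batch term the pericyte and smooth muscle median was -0.10. There TAGLN had -0.33, RGS5 0.16 (limma, adjusted p = 0.575) and CALD1 0.09 (0.678). With batch as a random effect RGS5, TAGLN and CALD1 missed the threshold (adjusted p = 0.0946, 0.292 and 0.0555). RGS5, a pericyte marker, rose by 1.09 ± 0.28, TAGLN by 0.96 ± 0.26 and CALD1 by 0.90 ± 0.19, the latter both actin-binding proteins of contractile cells. TAGLN also lost its call without SSc replicate 7 and without SSc replicate 13 (limma, adjusted p = 0.0502 in each).

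Eccrine gland, differentiated keratinocyte and melanocyte genes were lower as groups by camera with its preset correlation, not by a permutation test of list means chosen after seeing the data (adjusted p = 0.119, 0.234 and 0.234). All 9 eccrine gland genes tested had a negative log2 fold change, with a median of -1.19. None passed over all genes in limma, where 7 had an unadjusted p under 0.05, and 7 fell when adjusted over the list alone (camera, adjusted p = 0.000121; adjusted p = 0.301 with an estimated correlation). PIP (-2.86 ± 1.11) and SCGB1D2 (-1.98 ± 0.80), which encode secreted proteins, and the water channel gene AQP5 (-1.39 ± 0.59), all 3 chosen after their values were seen, had adjusted p of 0.158, 0.180 and 0.199 in limma. Differentiated keratinocyte genes had a median of -0.21 with 14 of 17 negative (camera, adjusted p = 0.00434, and 0.456 with an estimated correlation). None passed the threshold by limma over all genes or adjusted over the list alone, while 7 had an unadjusted p under 0.05. The differentiated keratinocyte call was lost without healthy replicate 12 (camera, adjusted p = 0.144) and with quantile normalization (median -0.09, adjusted p = 0.11). Melanocyte genes were negative in all 9 tested, with a median of -0.55, none past the threshold by either adjustment in limma and 0 with an unadjusted p under 0.05 (camera, adjusted p = 0.024; adjusted p = 0.676 with an estimated correlation). That call was lost without healthy replicate 13 (adjusted p = 0.067), 14 (0.19) or 15 (0.0527), and with batch as a random effect (median -0.31, adjusted p = 0.228). Adipocyte genes had a median of 0.69 with 14 of 18 positive, none past the threshold by either adjustment in limma and 2 with an unadjusted p under 0.05 (camera, adjusted p = 0.043; adjusted p = 0.763 with an estimated correlation). Without a batch term the adipocyte median was -0.06, and with the ACTB ratio of 3' to 5' signal as a covariate it was 0.03 while the test pointed lower. The adipocyte call was lost with batch as a random effect (median 0.32, adjusted p = 0.517), without healthy replicate 15 (adjusted p = 0.513) and without any of SSc replicates 5, 6, 8, 9, 10, 17 and 18 (0.0544 to 0.105). ADIPOQ, the adiponectin gene, had 1.03 ± 0.65 (limma, adjusted p = 0.422).

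The remaining 15 lists tested did not pass. In the Wnt list SFRP4 rose and WIF1 fell, and the median was 0.14 (camera, adjusted p = 0.395). CCN1, a matricellular protein, was the single riser of 19 immediate early genes (1.45 ± 0.32), with a list median of 0.03 (camera, adjusted p = 0.382). T cell and NK cell genes had a median of 0.26 with GZMK at 0.95 ± 0.52 (camera, adjusted p = 0.184), and B and plasma cell genes 0.38 with IGKC, the kappa light chain, at 1.71 ± 0.81 (camera, adjusted p = 0.0989). Without healthy replicate 12 both of these lists passed (camera, adjusted p = 0.00247 and 0.0121), and without healthy replicate 13 the second did (0.0356). B and plasma cell genes also passed with batch as a random effect (median 0.70, adjusted p = 0.0363), without the filter on dim genes (0.0472) and in the batch-adjusted table without a batch term (0.0448). Oxidative phosphorylation genes had a median of -0.09 with COX6C at -0.26 ± 0.09 (camera, adjusted p = 0.0989), and passed without healthy replicate 15 (0.0112). They also passed with the GAPDH ratio as a covariate (median -0.15, adjusted p = 0.00241), with the ACTB ratio (-0.23, 2.9e-05) and with the 9 SSc arrays without a letter A in the title (-0.15, 0.00281). Medians and adjusted camera p were 0.03 and 0.821 for stressed keratinocyte genes with S100A9 at 1.23 ± 0.80, -0.03 and 0.87 for proliferation genes with BUB1B at -0.22 ± 0.23, and -0.05 and 0.921 for fatty acid oxidation genes with PPARGC1A at -0.95 ± 0.43. They were -0.13 and 0.821 for dendritic and Langerhans cell genes with CD1B at -0.59 ± 0.49, -0.04 and 0.87 for sebaceous gland genes with HMGCS1 at -0.33 ± 0.47, and -0.10 and 0.504 for basal keratinocyte genes with KRT14 at -0.18 ± 0.09. Hair follicle genes had 0.32 and 0.504 with KRT35 at 1.24 ± 1.23, Schwann cell and nerve genes 0.10 and 0.532 with PMP2 at 0.38 ± 0.18, and skeletal muscle genes -0.19 and 0.743 with TNNI2 at -1.07 ± 0.46. With the ACTB ratio as a covariate sebaceous gland genes (median -0.87, adjusted p = 0.0345) and fatty acid oxidation genes (-0.14, 0.0187) passed. Mast cell genes had a median of -0.01, a mean of 0.02 and a test direction of lower (adjusted p = 0.959), with KIT, the stem cell factor receptor gene, at -0.65 ± 0.21 and 1 gene lower when adjusted over the list alone. Erythroid genes, of which 3 were measured, were not tested as a list, and HBD had -0.97 ± 0.46.

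**Figure D2:**
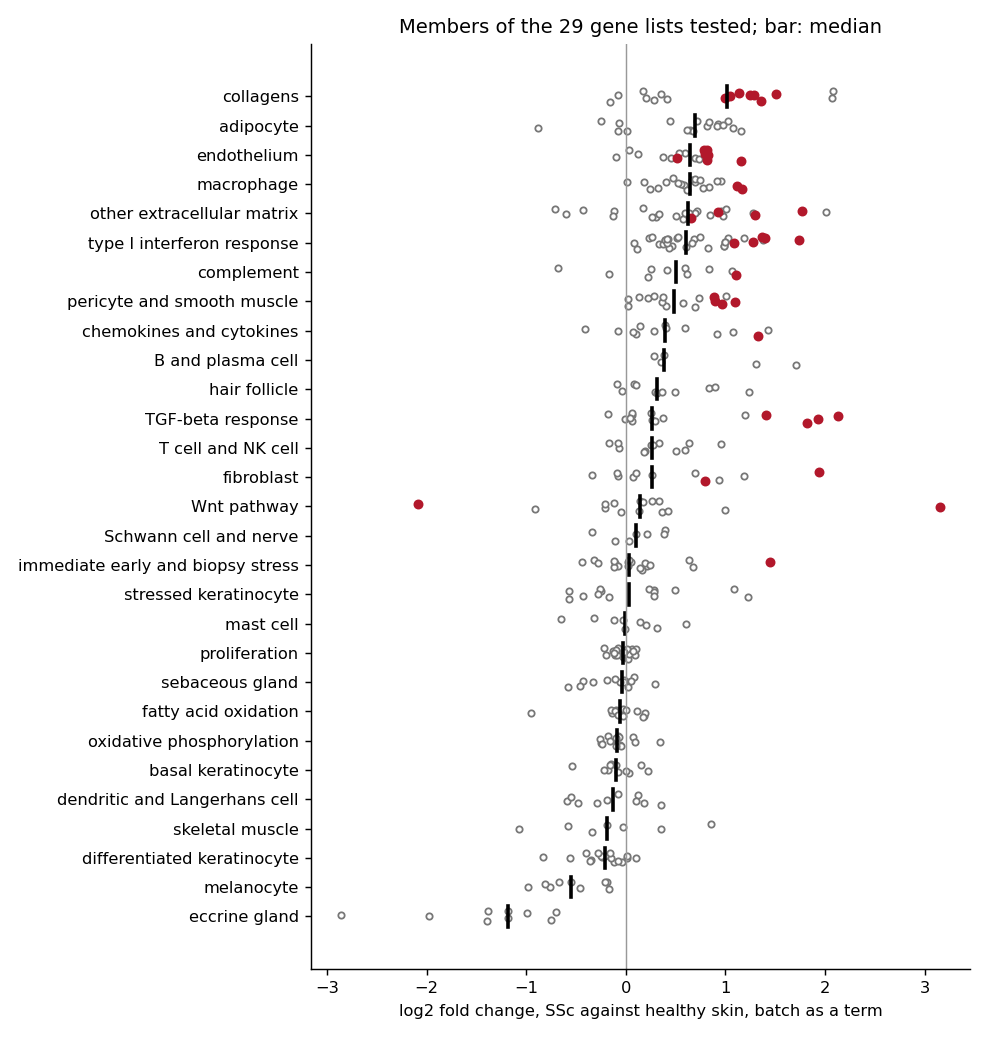
Log2 fold change of each member of the 29 lists tested, SSc against healthy skin with batch as a term, sorted by list median (black bar). Filled points passed an adjusted p of 0.05 in limma, as 7 of 16 collagen and 7 of 16 endothelium genes did, while none of the 9 eccrine gland genes did although all 9 lay below 0.

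RNA quality differed between the groups in part. The log2 ratio of the 3' to the 5' GAPDH control probe sets, which is higher where RNA is more degraded or its copying less complete, was 1.13 ± 0.21 (SD, n = 18) in SSc and 1.36 ± 0.14 (SD, n = 4) in healthy arrays of batch 2, a difference of -0.23 that missed the threshold (two-sided exact permutation test over 7315 splits, p = 0.0541). For ACTB the ratios were 4.22 ± 0.21 (SD, n = 18) and 4.72 ± 0.20 (SD, n = 4), a difference of -0.50 (two-sided exact permutation p = 0.000957). Both ratios were far lower in the healthy arrays of batch 4, at -0.05 ± 0.10 for GAPDH and 0.19 ± 0.12 for ACTB (SD, n = 3), and of batch 5, at -0.09 ± 0.19 and 0.38 ± 0.22 (SD, n = 8). With the GAPDH ratio as a covariate the list medians were 1.07 for collagens, 0.72 for other extracellular matrix, 0.70 for endothelium, 0.67 for type I interferon response, 0.70 for macrophage, -1.26 for eccrine gland and -0.55 for melanocyte genes. With it the adipocyte median was 0.26, and the adipocyte list no longer passed (camera, adjusted p = 0.61). Named genes lost their call in 7 cases with the GAPDH ratio and in 15 with the ACTB ratio. With the GAPDH ratio these included WIF1 (log2 fold change -2.05, adjusted p = 0.0557 in limma) and MMP27 (-0.97, 0.0556). TAGLN (1.04, 0.0522), CDH11 (0.83, 0.0753) and C1QB (1.18, 0.0752) were others. With the ACTB ratio they included IL6 (log2 fold change 1.24, adjusted p = 0.102 in limma), CCN1 (1.47, 0.0712), CD14 (1.22, 0.0676), COL1A1 (1.25, 0.109) and TIMP1 (1.14, 0.0541). WIF1 (-2.17, 0.105), IGFBP6 (-1.24, 0.0712), CALD1 (0.59, 0.221) and MCOLN3 (-0.97, 0.127) were others. ZNF273 had -0.68 with the GAPDH ratio (adjusted p = 0.146) and -0.41 with the ACTB ratio (0.591).

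**Figure D3:**
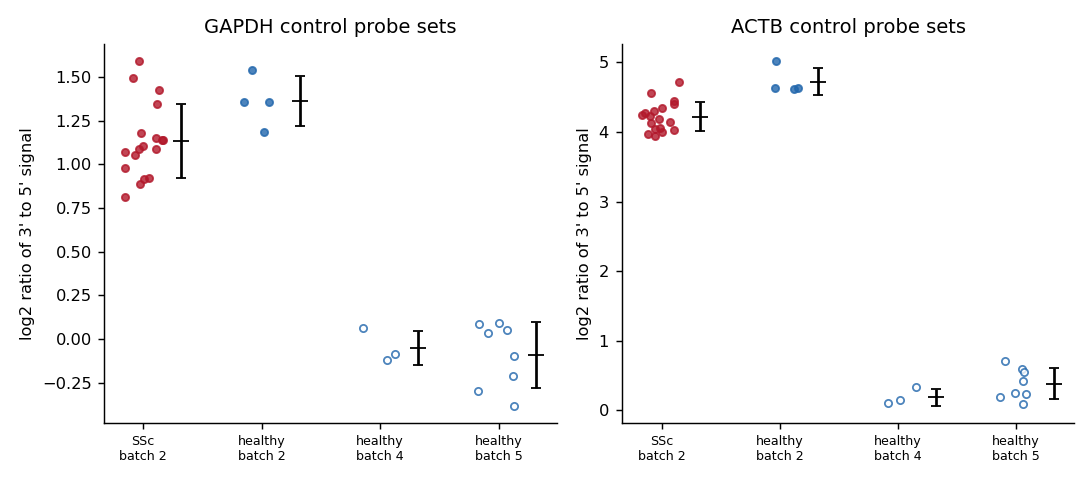
Log2 ratio of 3' to 5' signal of the GAPDH (left) and ACTB (right) control probe sets on each array by group and batch, with filled points for batch 2 and bars for the mean ± SD. In batch 2 the mean ACTB ratio was 4.22 in SSc and 4.72 in healthy skin, against 0.19 and 0.38 in batches 4 and 5.

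Among the 18 SSc arrays, all of batch 2, those with higher matrix expression also had higher macrophage and endothelial expression. The score of the other extracellular matrix list correlated with that of the macrophage list at Pearson r = 0.744 (permutation p = 0.00037, adjusted over 6 relations 0.00222) and Spearman rho = 0.711 (permutation p = 0.00132, adjusted 0.00792), and with that of endothelium at r = 0.721 (permutation p = 0.00086, adjusted 0.00258) and rho = 0.672 (permutation p = 0.00287, adjusted 0.00861). Without SSc replicates 7 and 11, the 2 arrays farthest from the median matrix score, r was 0.588 (permutation p = 0.0165) with macrophage and 0.587 (permutation p = 0.0169) with endothelium. With list members brighter than the median gene only, the endothelium relation passed by r (0.590, adjusted 0.0281) and not by rho (0.459, adjusted 0.136). There r without the 2 arrays farthest from the median was 0.362. T cell and NK cell genes gave r = 0.574 (permutation p = 0.0127, adjusted 0.0254) and rho = 0.591 (permutation p = 0.0112, adjusted 0.0223). Without those 2 arrays r was 0.310 (permutation p = 0.244), so this relation rests on them.

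The matrix score had no relation past the threshold with pericyte and smooth muscle genes (r = 0.465, permutation p = 0.0517, adjusted 0.0776; rho = 0.467, permutation p = 0.0512, adjusted 0.0769), although r was 0.593 without the same 2 arrays (permutation p = 0.0161) and rho passed given the GAPDH ratio of 3' to 5' signal (0.544, adjusted 0.0324). For type I interferon genes r was 0.319 (permutation p = 0.196, adjusted 0.235) and rho 0.340 (permutation p = 0.167, adjusted 0.201), and r was -0.014 without those arrays. For adipocyte genes r was 0.131 (permutation p = 0.605, adjusted 0.605) and rho 0.112 (permutation p = 0.654, adjusted 0.654), and r was 0.056 without them.

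**Figure D4:**
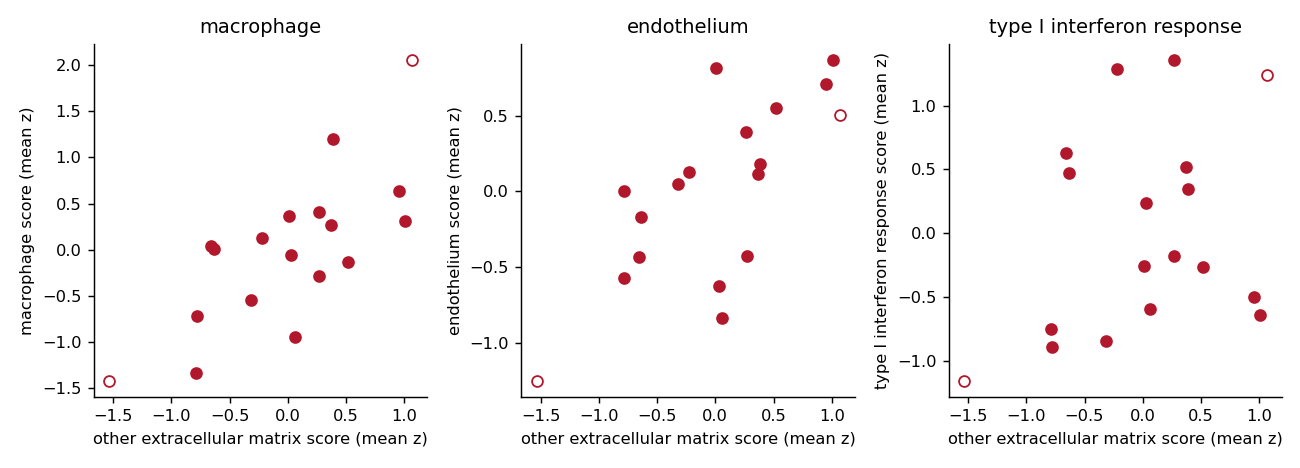
Scores of 3 gene lists against the score of the other extracellular matrix list across the 18 SSc arrays, each score being the mean over genes of the z-score over these arrays. Open points are SSc replicates 7 and 11, the 2 arrays farthest from the median matrix score, and r was 0.744 for macrophage, 0.721 for endothelium and 0.319 for type I interferon response.

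Healthy skin differed widely between batches. COL1A1 had a mean level of 8.86 in batch 2 (n = 4), 10.78 in batch 4 (n = 3) and 10.82 in batch 5 (n = 8), and TAGLN had 9.71, 11.51 and 11.45. CCL2, a chemokine gene for monocytes, had 8.80, 7.71 and 7.88. These 3 genes were chosen after their values were seen. Among the 15 healthy arrays 3218 of 9049 genes (35.6%) differed between batches 5 and 2 in limma at an adjusted p of 0.05 and 2395 between batches 4 and 2. In the deposited batch-adjusted table none differed between batches 5 and 2 in limma, where 1 gene had an unadjusted p under 0.05, and the median absolute difference between these batches was 0.025 against 0.31 before. Between SSc and healthy arrays of batch 2 the median absolute difference was 0.15 in both tables. Without a batch term the unadjusted values gave medians of 0.22 for endothelium (camera, adjusted p = 0.228), 0.33 for collagens (0.0528) and 0.13 for other extracellular matrix (0.385). These were among 9 called lists that lost their call there, and 3 others changed sign, while type I interferon response and macrophage genes passed. Fitted without a batch term, the batch-adjusted table called 2718 genes, 1277 higher and 1441 lower in SSc. The same fit of the values before adjustment called 4205 genes, 1718 higher and 2487 lower, and of the 220 genes above 150 were among them with the same direction and 6 with the opposite one.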

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

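Among the 4 healthy arrays of batch 2, 94 values (named genes and list scores) were searched for 1 array far from the other 3, and 6 were found, where chance alone gives about 4.7. Levels are log2(intensity + 16). IL6 was 4.46 on healthy replicate 15 against 5.39 to 5.55 on the others. CCL2 was 9.32 on healthy replicate 14 against 8.59 to 8.69. CD1B, an antigen-presenting molecule of dendritic cells, was 5.12 on healthy replicate 12 against 6.96 to 7.16. HMGCS1, an enzyme of cholesterol synthesis, was 11.13 on healthy replicate 14 against 9.28 to 9.59. The mean of the fatty acid oxidation genes was 9.98 on healthy replicate 14 against 9.59 to 9.64. The mean of the melanocyte genes was 9.57 on healthy replicate 12 against 10.65 to 10.81.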

How the results depend on the processing

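Leaving out each SSc array, the ACTB covariate and the division of SSc arrays by the letter A were chosen after seeing the data. Over all alternatives, 2211 of 2416 values of named genes and 1088 of 1156 list values stayed on the same side of the threshold with no called value changing sign; 48 of these, past the threshold in neither setting, changed sign. Of the others, 165 and 51 lost their call, 38 and 13 gained one, and 2 and 4 called values changed sign. The cause was not tested except where fewer arrays or a stricter threshold set it. Without a batch term 4205 genes passed (1718 higher, 2487 lower) and 2 lists, and the called values that changed sign were pericyte and smooth muscle (-0.10), fibroblast (-0.17) and adipocyte lists (-0.060), COL1A1 (-0.19) and TAGLN (-0.33). CALD1, LUM, CD14, PLVAP, RGS5, TIMP1 and C1QB lost their call there (limma, adjusted p between 0.0656 and 0.678). Batch 2 alone gave 131 genes (104 higher, 27 lower), batch as a random effect 408 (187 lower, with the calls of CALD1, COL1A1, RGS5, TAGLN and C1QB and of the fibroblast, adipocyte and melanocyte lists lost, and those of IFI44, CCL2 and the B and plasma cell list gained), the batch-adjusted values 365 with a batch term (254 higher, 111 lower) and 2718 without (1277 higher, 1441 lower), and array weights 473 (311 higher, 162 lower). The GAPDH covariate gave 142 genes (15 lower) and the ACTB covariate 125 (102 higher, 23 lower), with an adipocyte median of 0.028 and its test lower. A log2 fold change of at least 1 left 70 (58 higher, 12 lower). Without 1 array of batch 2 the count lay between 64 and 336 (57 to 249 higher, 7 to 87 lower), the lowest without healthy replicate 14 and the highest without SSc replicate 11. The 9 SSc arrays without the letter A gave 40 genes (38 higher, 2 lower), and the 9 with it 211 (127 higher, 84 lower). The GAPDH ratio was 1.26 ± 0.22 (SD, n = 9) in the former, 1.01 ± 0.11 (SD, n = 9) in the latter and 1.36 ± 0.14 (SD, n = 4) in healthy arrays of batch 2. With an estimated correlation 1 list passed, and by fry 7. With list members brighter than the median gene only, the matrix and T cell and NK cell scores had r = 0.442 (adjusted permutation p = 0.107), and rho with endothelium was 0.459 (adjusted permutation p = 0.136). Between healthy batches 5 and 2 the batch-adjusted table gave 0 genes in limma (1 with an unadjusted p under 0.05). The ACTB ratio differed by -0.50 (exact permutation p = 0.000957), and the GAPDH ratio in the batch-adjusted table by -0.23 (exact permutation p = 0.035). Testing all probe sets and averaging those of a gene were not run, because each gene had 1. Signal over background was not given in the tables used here, so what it limits is not known.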

Other observations

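The tests of keratinocyte share, of disease, of the list means by permutation and of the splits for single lists were chosen only after the results had been seen. Genes of the secretory pathway, which folds and exports proteins such as collagen, included some that rose in SSc skin. A list of 39 such genes, drawn up after the called genes were seen, held 9 that rose and none that fell in limma, with a median log2 fold change of 0.16. Its 30 members that had not been called were positive in 24 cases, with a median of 0.12. A list of 33 genes of the cilium and centrosome, drawn up in the same way, held 6 that fell and none that rose, with a median of -0.12, and 8 of its 27 uncalled members were positive. That either group moved as a whole is a hypothesis. Over the uncalled members, camera gave an adjusted p of 0.000211 for the secretory pathway and 0.0403 for the cilium, against adjusted p = 0.127 and 0.26 with an estimated correlation, and 7 and 14 of 100 splits of the 22 arrays gave a p as small. The bound set first asked for the camera p alone, and the splits were added as a second one after that p was seen. Camera called a median of 9 lists in the other splits, so its p alone does not exclude chance here and both hypotheses stay open.

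The first pattern is the higher expression of matrix, endothelial, interferon and macrophage genes. For the count of 220 genes chance is unlikely, since 1 of 100 splits of the 22 batch 2 arrays, the real one, gave as many. That is the smallest share that 100 splits can give. The highest other split gave 115, and a split with 0 healthy arrays among its 4 gave 63. For the count of 14 lists chance stays open, since 22 of 100 splits gave as many and the highest other gave 20. An exact permutation test of each list's mean, adjusted over the 29 lists, passed for collagens (0.00595), endothelium (0.00595) and TGF-beta response (0.0145). It passed for other matrix, interferon, pericyte and fibroblast genes as well (0.0476 each). The other called lists did not pass: macrophage (0.117), complement (0.119), eccrine gland (0.119), chemokine and cytokine (0.228), adipocyte, differentiated keratinocyte and melanocyte genes (0.234 each). Camera p was as small in 1 of 100 splits, the real one, for endothelium, 3 for collagens and TGF-beta response, and 4 for pericyte genes. It was so in 6 for other matrix, 7 for fibroblast, 9 for macrophage and 10 for interferon genes, and in 11 to 50 for the remaining called lists. By that count fibroblast, macrophage and interferon genes did no better than the secretory pathway list above. With the GAPDH ratio as a covariate the median over the 111 members of these lists was 1.11 times that without it. With the ACTB ratio, chosen after seeing the data, it was 1.32 times. The median did not shrink, which argues against RNA quality as the whole cause as far as these ratios measure it. Of the 220 genes, 126 kept their call with the GAPDH ratio and 83 with the ACTB ratio. The 95% bootstrap interval for the GAPDH ratio, 1.04 to 1.23, was drawn over genes, which move together. It leaves out the spread between arrays. For a lower share of keratinocyte RNA the comparison made cannot decide. The median of endothelium and macrophage members exceeded that of 5 other cell type lists by 0.81 (bootstrap over genes, 0.60 to 1.15). Those were T cell and NK cell, mast cell, dendritic and Langerhans cell, melanocyte and eccrine gland genes. They were picked after eccrine gland and melanocyte genes had been called lower, which set the outcome in part. Differentiated keratinocyte genes had a median of -0.21, so this share stays open. Disease and other differences between the donors of the 4 healthy and 18 SSc arrays cannot be told apart.

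The second pattern is the 2718 genes called in the batch-adjusted table without a batch term, against 365 with one. After the adjustment the healthy arrays of batches 4 and 5 lay near those of batch 2, with median absolute differences of 0.041 and 0.025. Values of batch 2 moved too, and the GAPDH ratio of its healthy arrays went from 1.36 to 0.93. The method was not given, so it is an inference that the 4 healthy arrays of batch 2 set the level of the other 11. If so, these 11 arrays may count as independent where they are not. When 4 SSc arrays stood in for the healthy arrays of batch 2 and the 11 others were moved onto their mean, so that no group differed, 20 draws called a median of 255.5 genes without a batch term (15 to 1490) and 0 with one (0 to 1). That is a candidate explanation for part of the 2718. The stand-ins were SSc arrays, whose spread need not match that of the healthy arrays they replaced. The number called may therefore differ from that for healthy arrays. The draws stay below 2718, and how many of its genes reflect a real difference was not tested.

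The third pattern is the lower level of eccrine gland and melanocyte genes. How much gland a biopsy happens to hold may account for the eccrine part. It was not tested for melanocyte genes, whose mean had a two-sided exact permutation p of 0.106. The eccrine mean lay between 6.91 and 11.42 in SSc and between 10.29 and 11.10 in healthy skin of batch 2 (two-sided exact permutation p = 0.0369). The bound set in advance, p under 0.05, did not allow for the choice of this list among 29, and adjusted over them, a step added after that p was seen, it was 0.119, so this stays open. With the GAPDH ratio as a covariate the median over both lists was -0.87 (95% bootstrap interval over genes -1.14 to -0.57). With the ACTB ratio it was -1.11, against -0.79 without either, so it did not shrink. The size set in advance was narrowly missed by that interval. Both lists passed in camera with either ratio, a reading added after the value was seen, and camera's p alone does not exclude chance here. The bound for RNA quality as the cause, also set in advance, was a median above -0.3, and the whole interval lay below that. For these genes the values argue against RNA quality as the whole cause, as far as these ratios measure it. The interval leaves out the spread between arrays, and chance stays open. Disease was not tested apart from gland content.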
